A study of Oryza sativa with 6 samples.

How the data were processed

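RNA-seq of rice leaves at 0, 48 and 96 h of drought in IR20 and Mahulata gave 6 libraries, 1 per variety and time, so every group has n = 1. Per the submitters' processing notes, Trimmomatic, TopHat2, Cufflinks and Cuffdiff were used; their versions, roles and parameters are not given in the sources used here. The genome build and annotation are not given in the sources used here either. The deposited tables pair 2 libraries each: 4 set a drought time against 0 h within a variety and 3 set Mahulata against IR20 at the same time. Per the file headers each holds FPKM per library, a fold column and a p-value.

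FPKM was computed by the authors and used as deposited. The authors' fold column is headed as a natural log, but its values equal the log2 of the deposited FPKM ratio. The deposited p-value comes from 1 library per side, and was not used further. The authors' up and down lists were counted, and supplied unrounded values for 1 table as said below. Tables were scaled separately: the same library differed between tables by constant factors from 0.949 to 1.08, and after that factor 0.017% to 8.91% of genes differed by over 1.5 times in FPKM + 1. The 3089 genes concerned in any pair are named as such where they are reported. All comparisons within a pair use 1 table. One consequence of the authors' scaling is that a gene's FPKM depends on what the most abundant genes take, so counts and list medians were also computed on rescaled values, those of the marker lists after the data were seen. The correlation and overlap of the varieties were not.

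Isoform rows of a gene repeat 1 value, save for 1 or 2 genes per table, so each gene was counted once. The 7 tables hold 35258 gene identifiers, with names as annotated in the files. Some different genes share both value and locus with another gene, from 104 to 698 of them per comparison. They were kept as separate genes in counts and lists, so 1 measured locus can enter more than once. The effect of this on counts and list medians was not tested. Per comparison 4 to 12 genes carry a fold of 0 and a p-value of 1 although their deposited FPKM differ; they were taken as untested and left out. Lists of genes not expressed in the IR20 tables hold FPKM of 0 only and enter no comparison. The table of Mahulata at 96 h against 0 h holds a sheet rounded to 2 decimals, and unrounded values were taken from its up and down sheets where present.

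The difference per gene was that of log2(FPKM + 1), later time minus 0 h or Mahulata minus IR20, over genes whose higher value was at least 1 FPKM. Genes with a difference of at least 1 (2-fold) were counted. The difference of responses was the Mahulata difference minus the IR20 difference. No count test was run, since the files hold no counts. For 29 gene lists chosen before the data were examined, the median difference was given its percentile among 10000 random lists of the same size matched in 10 bins of mean expression; a list stood apart below 2.5 or above 97.5. The percentile describes these libraries and is no test across plants. With 234 list medians computed this way, about 5% would fall outside by chance if the members of a list moved independently. The lists covered LEA and dehydrin genes, abscisic acid synthesis and breakdown, clade A phosphatases 2C, stress transcription factors, heat shock, osmolytes, reactive oxygen, glutathione S-transferases, aquaporins, photosystems, the Calvin cycle, chlorophyll synthesis, senescence, cell wall, cell division, ribosomal proteins, wax and lipid transfer, jasmonate, ethylene, auxin, pathogenesis-related genes, nitrogen, sugar and starch, autophagy and the clock. Checks were root markers, meristem and panicle markers, housekeeping genes and transposon-annotated genes. Shorter marker lists (cytosolic and plastid ribosomes, light-harvesting and plastocyanin-like proteins, grain storage and grain maturation proteins, and nuclear copies of plastid-genome genes) were written after the files had been opened.

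Genes were named by a rule set before the data were examined. It takes the 5 largest increases and decreases per comparison among functionally annotated genes at 5 FPKM or more, up to 3 members with the largest difference per list, and members of lists given by identifier. The procedure was tested on simulated data made from the IR20 48 h comparison of 17224 genes. Differences were shuffled among genes of like expression and lists were drawn at random, so genes that move together were not simulated. The rates with no shift are thus near the limits by construction, and do not give the rate of false calls for lists of co-regulated genes. Lists of 10 genes with no shift were called above in 1% and below in 2.5% of 200 draws, and those shifted by 1 were called above in 71.5%; lists of 50 shifted by 1 were called above in 100%. Of 100 genes planted 3-fold each way among 15410 genes, 96 of the raised and 70 of the lowered were recovered, and 121 of the 122 that lay at 5 FPKM or more. Alternatives tried were a pseudocount of 0.1, no floor, a floor of 5 FPKM, rescaling each pair, a 4-fold threshold, genes above 0 in both libraries only, and the authors' deposited lists. Added after the data were seen were keeping untested genes, leaving out genes that differ between tables, counting transcripts, building the variety difference across tables, and splitting the photosystem and plastid ribosomal lists. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.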

Results

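Rice leaves were profiled by RNA-seq in 2 varieties, IR20 and Mahulata, at 0, 48 and 96 h of drought in the early vegetative stage. IR20 is a semi-dwarf indica variety and Mahulata is a landrace. Each of the 6 groups held 1 library, so no difference has a replicate check, and no p-value or standard deviation was computed. Expression is given as FPKM, and differences are on the log2(FPKM + 1) scale, which understates the change of low genes. "Higher" and "lower" mean at least 2-fold on that scale unless a list median is meant. Gene positions are locus intervals as the files give them, and a locus can hold more than 1 gene. The genome build is not given in the sources used here.

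The files hold no read counts, so absolute depth is unknown. The smallest FPKM steps of low genes gave depths relative to the IR20 library at 0 h of 0.903 for IR20 at 48 h, 0.726 for IR20 at 96 h, 0.618 for Mahulata at 0 h, 0.648 for Mahulata at 48 h and 0.934 for Mahulata at 96 h, if those steps are single fragments. Values near the floor were therefore coarsest in the Mahulata 0 h and 48 h libraries. The 100 most abundant genes took 51.1% of all FPKM in IR20 at 0 h, 31.3% at 48 h and 42.3% at 96 h. In Mahulata they took 51.2%, 32.9% and 36.5%. As that share fell, the median of all genes was above 0 in each drought comparison, at 0.52 and 0.42 in IR20 and at 0.67 and 0.36 in Mahulata, for 48 h and 96 h. List medians are set against expression-matched random lists, which carry the same shift. A rescaled median is one computed after each pair of libraries was brought to a median ratio of 1.

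The first comparison asked how the IR20 leaf transcriptome changed with drought. LEA proteins and dehydrins, small hydrophilic proteins that accumulate in drying cells and seeds, had the highest list medians. Of the measured members, 23 of 26 were higher at 48 h and 22 of 27 at 96 h, with medians of 5.75 and 6.88. Chlorophyll synthesis enzymes moved the other way, with 7 of 7 lower at 48 h (median -3.24) and 7 of 7 at 96 h (median -7.05). Genes for chlorophyll a-b binding proteins, the antennae of the photosystems, were lower in 13 of 17 cases at 48 h and in 16 of 17 at 96 h. Aquaporins, the water channels, were mostly lower only by 96 h.

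Dehydrin genes lay side by side on chromosome 11 and were among the largest increases. LOC_Os11g26750 went from 0.472 to 1075 FPKM at 48 h (9.51) and reached 14155 FPKM at 96 h. LOC_Os11g26780 went from 8.45 to 6836 FPKM at 48 h and was at 23144 FPKM at 96 h. LOC_Os11g26790 (chromosome 11, 15342563 to 15343857) went from 17.4 to 10246 FPKM at 48 h; at 96 h it is listed at 0 with a fold of 0, the mark of an untested gene, and that value was not used. The LEA gene LOC_Os05g46480 (chromosome 5, 26927606 to 26928902) went from 11.3 to 5137 FPKM, and LOC_Os03g17790, annotated OsRCI2-5, from 4.78 to 2609.9 FPKM. At 96 h the seed maturation protein PM41 gene LOC_Os01g46600 had gone from 3.41 to 21529 FPKM and LOC_Os05g47730, a lipid transfer protein family member annotated LTPL153, from 2.06 to 8558 FPKM. The largest difference of all genes at 96 h was that of LOC_Os07g29230 (LTPL63), listed at 0 at 0 h and at 11099.5 FPKM at 96 h; it is absent from the other table of that library, so the value rests on 1 table.

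All 9 clade A protein phosphatases 2C, the negative regulators of abscisic acid signalling that the hormone itself induces, were higher at both times, with medians of 3.53 and 2.84. LOC_Os05g49730 went from 0.245 to 61.9 FPKM at 48 h and LOC_Os03g16170 from 5.44 to 168 FPKM. Among the stress transcription factors 10 of 14 were higher at 48 h and 10 of 14 at 96 h (medians 3.24 and 2.88). The NAC gene LOC_Os11g03300 went from 1.44 to 209 FPKM at 48 h, and the DREB gene LOC_Os06g03670 from 0.465 to 108 FPKM at 96 h. The bZIP gene LOC_Os02g52780 went from 12.1 to 217 FPKM at 48 h, whereas the DREB gene LOC_Os09g35010 went from 5.89 to 0.475. The list of abscisic acid synthesis and breakdown genes did not stand apart (medians 1.33 and 0.47), and its members split. Of the 9-cis-epoxycarotenoid dioxygenases, the rate-limiting enzymes of abscisic acid synthesis, LOC_Os07g05940 went from 0.139 to 58.4 FPKM at 96 h while LOC_Os02g47510 went from 258 to 0.21 FPKM.

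The photosystem list as fixed had medians of -0.32 and -0.40, with plastocyanin-like members at -0.37 and -0.41 and nuclear copies of plastid-genome genes at 0.37 (-0.09 rescaled) and 0.66. Without both kinds 30 of 38 genes were lower at 48 h and 36 of 38 at 96 h, with medians of -1.85 and -6.27 (-2.52 and -6.84 rescaled). The chlorophyll a-b binding protein gene LOC_Os01g52240 (chromosome 1, 30030996 to 30041476) went from 13879.8 to 121 FPKM at 48 h and was at 3.94 FPKM at 96 h. LOC_Os01g41710, of the same family, went from 17012 to 12.9 FPKM at 96 h. The glyceraldehyde-3-phosphate dehydrogenase gene LOC_Os04g38600 went from 9868 to 6.37 FPKM, and LOC_Os03g56930, annotated app1, from 1944 to 0.0264 FPKM. Protochlorophyllide reductase A, the light-dependent step of chlorophyll synthesis (LOC_Os04g58200), went from 963 to 4.6 FPKM at 48 h. The magnesium chelatase gene LOC_Os03g36540 went from 379 to 1.59 FPKM at 96 h. The Calvin cycle list had medians of -0.14 at 48 h and 0.05 at 96 h (-0.81 rescaled), below matched lists at 48 h only. At 96 h the list was split, with 11 of 25 higher and 11 lower (quartiles -3.98 and 2.49). Its members annotated as plastid-genome genes were not set apart, unlike those of the photosystem list. The transketolase gene LOC_Os04g19740 went up from 0.512 to 167 FPKM and a fructose-1,6-bisphosphatase-type gene, LOC_Os03g16050, went down from 809 to 5.21 FPKM.

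Senescence and chlorophyll breakdown genes stood above matched lists at 48 h, with 7 of 8 higher (median 3.60), and not at 96 h, with 6 of 8 higher (median 2.02). The stay-green gene LOC_Os09g36200, which acts in chlorophyll breakdown, went from 4.74 to 162 FPKM at 48 h. Heat shock proteins were higher in 59 of 108 cases at 48 h and 58 of 115 at 96 h (medians 1.10 and 1.03), with 4 and 20 lower. Among them was the small heat shock gene LOC_Os03g15960 (13.9 to 717 FPKM at 48 h). Rescaled, 36 of 106 were higher and 11 lower at 48 h, and 38 of 113 higher and 26 lower at 96 h. The rescaled medians were 0.52 and 0.58, still above matched lists. Autophagy genes were higher in 7 of 13 cases at 48 h (median 1.23, 0.71 above all genes) and had a median of 0.57 at 96 h. The 48 h call lay at the limit, at percentile 97.7. It ended on rescaling (0.61, percentile 97.4, just short of the limit), with a pseudocount of 0.1 FPKM (percentile 94.5), with a floor of 5 FPKM (96.8) and without genes that differ between tables (97.465). Osmolyte synthesis genes had medians of 1.05 and 1.22, not apart from matched lists. In that list LOC_Os01g62900, annotated as an amino acid kinase, went from 2.27 to 172 FPKM at 96 h.

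Cell wall expansion genes were lower in 25 of 43 cases at 48 h and 24 of 44 at 96 h (medians -1.38 and -1.31), led by the expansin LOC_Os10g40720, from 226 to 0.762 FPKM at 48 h. Auxin response genes were lower in 27 of 63 and 38 of 65 cases (medians -0.63 and -1.19), and the SAUR gene LOC_Os09g37480 went from 57.7 to 1.21 FPKM at 48 h. Nitrogen assimilation genes had medians of -1.10 and -1.48, the second not apart among genes above 0 in both libraries (-0.68, percentile 4.42). The nitrate reductase LOC_Os08g36480 went from 95.5 to 0.171 FPKM at 96 h, and the asparagine synthetase LOC_Os03g18130 went up from 1.80 to 37.2 FPKM at 48 h. Aquaporins had a median of 0.00 at 48 h and of -2.71 at 96 h, where 19 of 23 were lower. Rescaled, the 48 h median was -0.77, below matched lists (percentile 1.69), with 9 of 24 lower and 1 higher. LOC_Os09g36930 went from 764 to 8.09 FPKM at 48 h, and LOC_Os10g35050 went the other way, from 0.0925 to 286 FPKM at 96 h. Ethylene synthesis genes lay below matched lists (medians -0.37 and -1.40), though at 48 h not with a floor of 5 FPKM (0.15, percentile 6.75). Glutathione S-transferases had medians of 0.85 and -0.64, the second below matched lists, a call lost with no floor (-0.0169, percentile 12.9), among genes above 0 in both libraries (-0.0309, percentile 9.97) and without genes that differ between tables (-0.34, percentile 3.16). Ribosomal protein genes had a median of 0.58 at 48 h (-0.02 rescaled) and -0.32 at 96 h, the second below matched lists.

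Wax, cutin and lipid transfer genes had medians of 0.39 (-0.21 rescaled) and -0.82, below matched lists at 96 h. Sugar and starch genes had medians of 0.40 (-0.09 rescaled) and 0.92, and the sucrose synthase LOC_Os03g22120 went from 4.47 to 717 FPKM at 96 h. Pathogenesis-related genes had medians of 0.88 and 0.84, not apart from matched lists. Rescaled, they stood above matched lists at both times (0.38, percentile 98.3, and 0.53, percentile 97.8). The thaumatin gene LOC_Os03g46060 went from 5.81 to 1121 FPKM at 96 h. Reactive oxygen scavenging genes had medians of 0.49 (-0.24 rescaled) and -0.13; the catalase LOC_Os02g02400 went from 100.4 to 4.37 FPKM at 48 h. Jasmonate genes had medians of 0.02 and 0.30 (-0.48 and -0.26 rescaled), and clock genes of 0.02 (-0.64 rescaled) and 0.73. At 96 h 4 of 8 clock genes were higher and 2 lower, with the response regulator genes LOC_Os07g49460 going from 29.7 to 2.14 FPKM and LOC_Os11g05930 from 5.24 to 37.9 FPKM. A shift of clock phase at 96 h was not separated from drought here, and it would bear on light-regulated genes such as those of light harvesting. Cell division and histone genes had medians of 0.04 and 0.27 (-0.55 and -0.25 rescaled), below matched lists at 48 h. Genes annotated as transposons had medians of 0.48 (-0.08 rescaled) and 0.96, above matched lists at 96 h. Of the largest decreases outside these lists, the dirigent gene LOC_Os11g42550 went from 252 to 0.0333 FPKM and the protein kinase gene LOC_Os11g35274 from 193 to 0.773 FPKM at 48 h.

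In all, IR20 had 5384 genes at least 2-fold higher and 2683 at least 2-fold lower among 17224 genes at 48 h, and 6746 higher and 4760 lower among 18035 at 96 h. After rescaling the counts were 2608 higher and 3833 lower at 48 h, and 4715 and 5811 at 96 h, so the share of higher genes went from 66.7% to 40.5% and from 58.6% to 44.8%. The authors' deposited table lists 2050 genes up and 1332 down at 48 h, and 2504 up and 2040 down at 96 h.

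**Figure D1:**
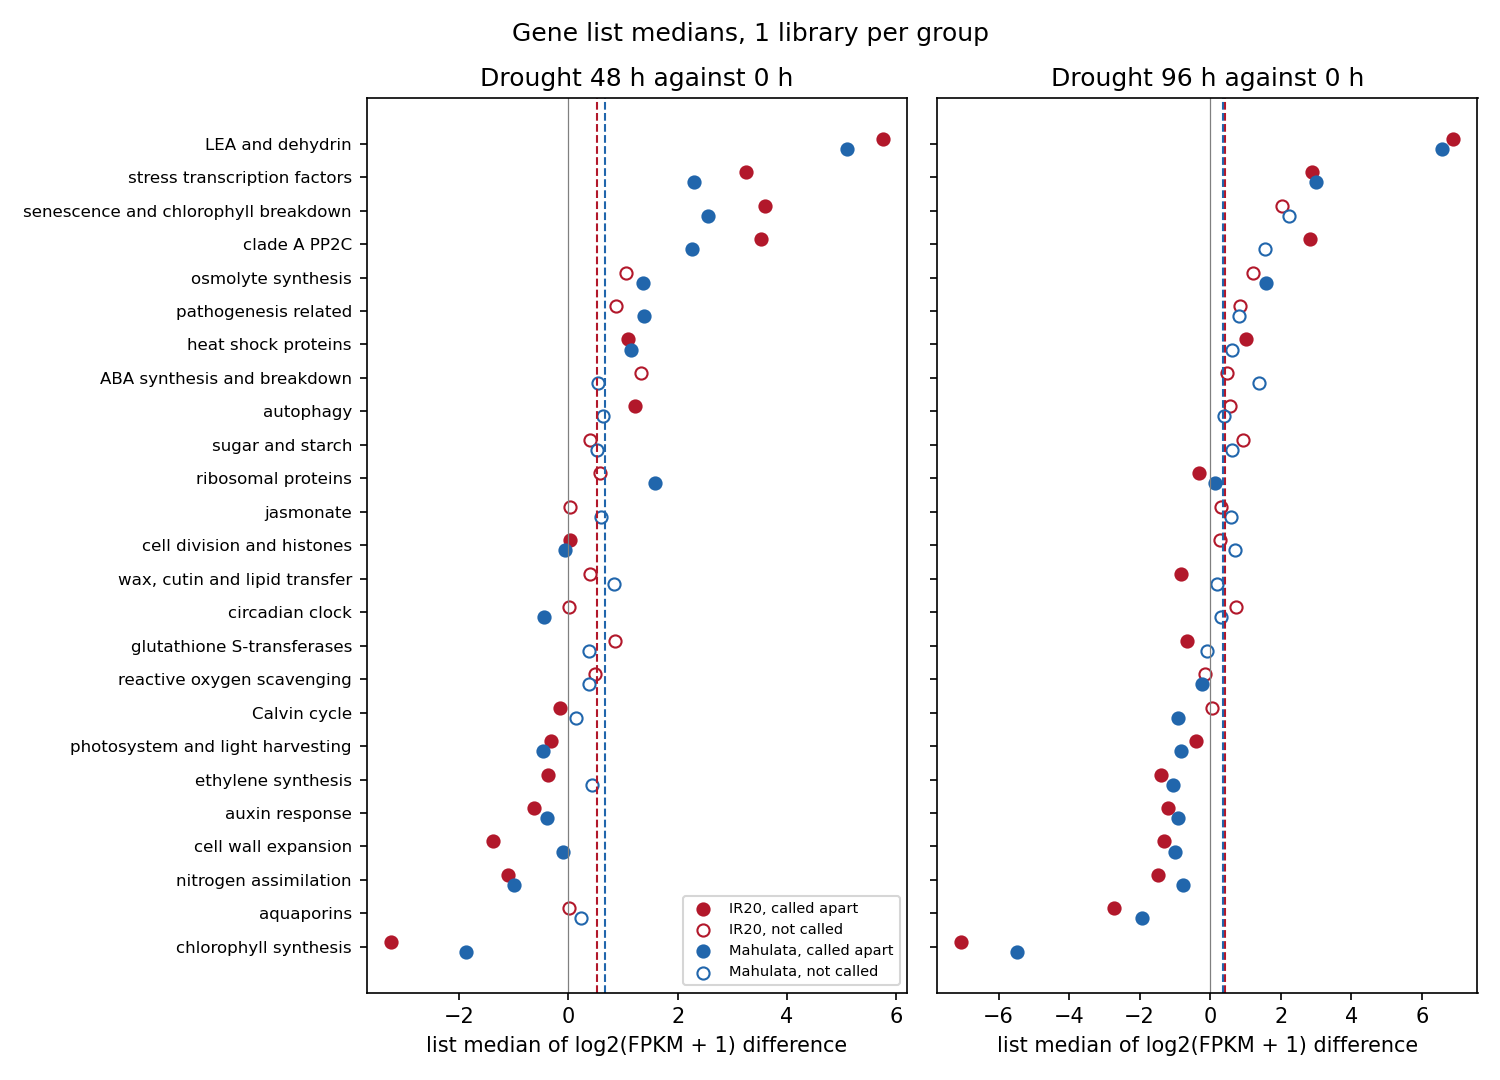
Median difference of each gene list from 0 h (x axis, log2(FPKM + 1)) at 48 h (left) and 96 h (right), IR20 in red and Mahulata in blue, filled where the list stood apart from matched random lists. Dashed lines are the medians of all genes; LEA and dehydrin genes lie farthest right, at 6.88 and 6.57 at 96 h, and chlorophyll synthesis genes farthest left, at -7.05 and -5.48, while ribosomal protein genes in Mahulata at 96 h, at 0.14, turn to -0.36 on rescaling.

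The second comparison asked the same of Mahulata. LEA and dehydrin genes again had the highest medians, 5.09 at 48 h and 6.57 at 96 h, with 23 of 26 and 23 of 27 members higher. All 7 chlorophyll synthesis genes were lower at both times (medians -1.87 and -5.48). Chlorophyll a-b binding protein genes were lower in 13 of 17 cases at 48 h (median -2.05) and 16 of 17 at 96 h (-7.19). Ribosomal protein genes were higher in 239 of 347 cases at 48 h, with a median of 1.59, above all matched lists.

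The LEA gene LOC_Os05g46480 went from 2.42 to 5809 FPKM at 48 h (10.73) and reached 21743 FPKM at 96 h. The dehydrins LOC_Os11g26750 and LOC_Os11g26790 went from 0.101 to 1426 and from 8.74 to 11766 FPKM at 48 h; LOC_Os11g26790 is listed at 0 at 96 h as an untested gene here too, and that value was not used. At 96 h the PM41 gene LOC_Os01g46600, listed at 0 at 0 h, was at 10589 FPKM, the LEA group 1 gene LOC_Os04g49980 had gone from 0.43 to 8061 FPKM, and the dehydrin LOC_Os11g26570 from 0.217 to 3107 FPKM. An inhibitor I family gene, LOC_Os01g42860, went from 7.53 to 4801 FPKM at 48 h.

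Clade A phosphatases 2C were higher in 7 of 9 cases at 48 h (median 2.26) and 6 of 9 at 96 h (median 1.55, percentile 89.1, not apart). LOC_Os05g49730 went from 0.0289 to 84.2 FPKM at 96 h, while LOC_Os01g62760 went from 44.1 to 53.5 FPKM. Stress transcription factors were higher in 10 of 12 and 10 of 13 cases (medians 2.29 and 3.0), the DREB gene LOC_Os06g03670 going from 0.555 to 115 FPKM at 96 h. Abscisic acid synthesis and breakdown genes had medians of 0.55 (-0.14 rescaled) and 1.38, and again LOC_Os07g05940 went up, from 0.351 to 44 FPKM at 48 h, and LOC_Os02g47510 down, from 148 to 0.27 FPKM at 96 h. Osmolyte synthesis genes stood above matched lists at both times (1.37 and 1.57), but not with no floor (0.63, percentile 81.2, and 0.53, percentile 85.2) or without genes that differ between tables (0.96, percentile 79.5, and 0.53, percentile 63.2), with LOC_Os01g62900 going from 0.548 to 252 FPKM. Heat shock proteins were higher in 62 of 111 cases at 48 h (median 1.14). Rescaled, 37 of 106 were higher and 16 lower at 48 h (median 0.50, still above matched lists). At 96 h their median of 0.62 did not stand apart. Senescence genes were higher in 6 of 7 cases at 48 h (median 2.55), and the stay-green gene LOC_Os09g36200 went from 18.6 to 143 FPKM; their median at 96 h was 2.24, not apart. Pathogenesis-related genes stood above matched lists at 48 h (1.38, 27 of 49 higher), a call lost with no floor (0.16, percentile 25.1), and not at 96 h (0.81).

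The nuclear photosystem genes, taken without plastocyanin-like proteins and plastid-genome copies, were lower in 30 of 38 cases at 48 h and 36 of 38 at 96 h (medians -2.01 and -5.75). The list as fixed had medians of -0.46 and -0.84, below matched lists. LOC_Os01g52240 went from 7408 to 20.9 FPKM at 48 h and was at 1.64 FPKM at 96 h. The Calvin cycle list stood below matched lists at 96 h (-0.91; 0.14 at 48 h, -0.44 rescaled), but not with no floor (-0.13, percentile 3.26) or without genes that differ between tables (-0.32, percentile 3.43). The Calvin list was split here too at 96 h, with 8 of 26 higher and 13 lower (quartiles -4.44 and 1.49). Its difference of responses at 96 h did not stand apart (-0.16, percentile 21.7). The Rubisco small subunit gene LOC_Os12g19470 went from 3173 to 7.25 FPKM at 96 h. The glycine cleavage H protein gene LOC_Os10g37180, of photorespiration, went from 2294 to 0.807 FPKM. Protochlorophyllide reductase A (LOC_Os04g58200) went from 372 to 4.19 FPKM at 48 h.

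Among the ribosomal protein genes the 40S and 60S genes of the cytosolic ribosome were higher in 122 of 125 cases at 48 h (median 2.04, 1.32 rescaled), against 23 of 123 in IR20 (median 0.68, 0.03 rescaled). Their medians at 96 h were 0.29 in Mahulata (-0.29 rescaled) and -0.63 in IR20. Nuclear 30S and 50S genes of the plastid ribosome had medians of -0.17 at 48 h and -1.65 at 96 h in Mahulata, and of -0.51 and -1.62 in IR20. These genes were taken as plastid by annotated name only, and they were split at 48 h. In Mahulata 9 of 22 were higher and 8 lower, and in IR20 4 of 22 were higher and 9 lower. At 96 h 12 of 23 were lower in each variety, with 1 higher in Mahulata and 2 in IR20. The plastid ribosomal gene LOC_Os02g43600 (L19) went from 234 to 0.595 FPKM at 96 h in Mahulata and from 453 to 2.49 FPKM in IR20. The whole ribosomal list in Mahulata at 96 h had a median of 0.14, which turned to -0.36 on rescaling and lay below matched lists either way.

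**Figure D2:**
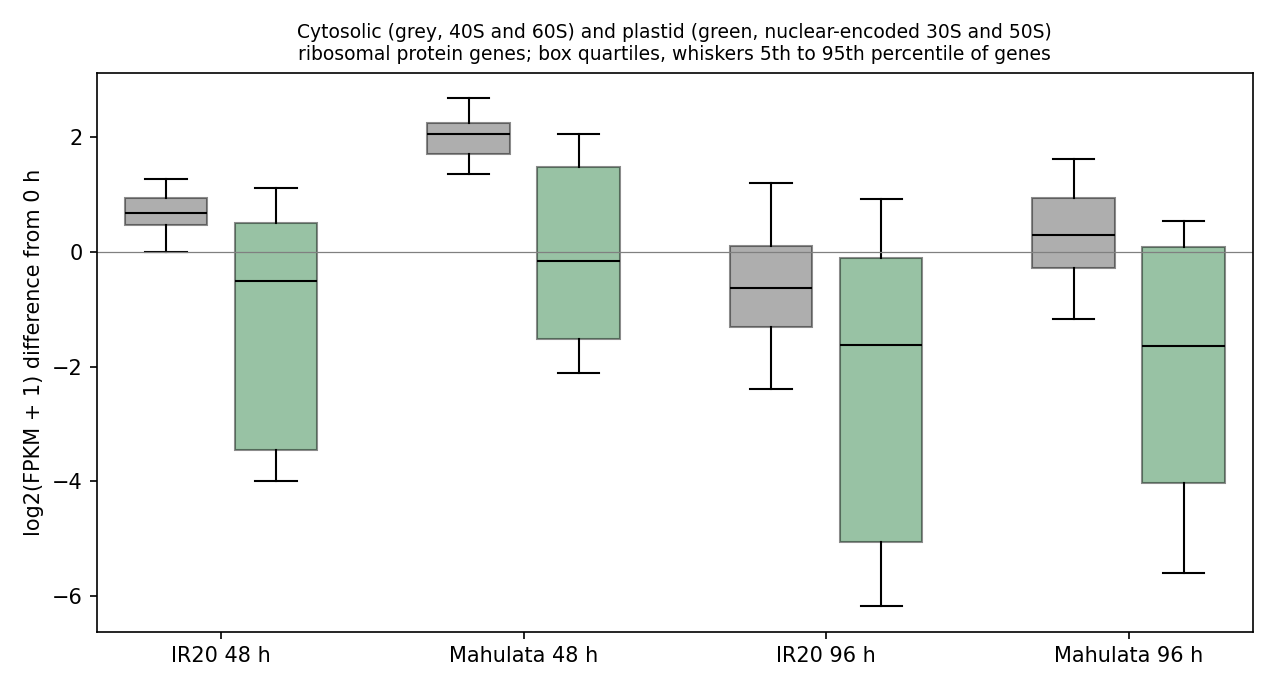
Log2(FPKM + 1) difference from 0 h (y axis) of cytosolic ribosomal protein genes (grey) and nuclear-encoded plastid ribosomal protein genes (green) in each variety and time (x axis); boxes are quartiles over genes, lines medians, and whiskers the 5th to 95th percentile of genes. The grey box of Mahulata at 48 h is the highest, with a median of 2.04, and the median of Mahulata at 96 h, 0.29, turns to -0.29 on rescaling.

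Aquaporins had a median of 0.23 at 48 h (-0.58 rescaled) and -1.93 at 96 h, where 19 of 23 were lower; LOC_Os09g36930 went from 1521 to 16.7 FPKM at 48 h. Cell wall expansion genes had medians of -0.11 and -0.98, auxin response genes of -0.38 (0.21 with a floor of 5 FPKM) and -0.91, and nitrogen assimilation genes of -1.0 and -0.76, all below matched lists. The nitrogen call at 96 h was lost with no floor (-0.27, percentile 4.64) and without genes that differ between tables (-0.64, percentile 4.19). The nitrate reductase LOC_Os08g36480 went from 125 to 0.689 FPKM and the expansin LOC_Os10g40720 from 124 to 0.0927 FPKM at 96 h. Cell division genes lay below matched lists at 48 h (-0.05; 0.0171 with no floor) and had a median of 0.71 at 96 h. Clock genes lay below at 48 h with no member 2-fold apart (-0.45; rescaled -1.07, with 4 of 7 lower; percentile 1.83, and 2.61 with no floor and 2.62 with untested genes kept, neither apart). At 96 h their median was 0.31 (-0.25 rescaled), and as in IR20 LOC_Os07g49460 went down, from 28.3 to 1.96 FPKM, and LOC_Os11g05930 up, from 7.56 to 40.1 FPKM. Ethylene synthesis genes had medians of 0.43 (-0.31 rescaled) and -1.05, below matched lists at 96 h. Reactive oxygen scavenging genes had medians of 0.38 (-0.26 rescaled) and -0.24, the latter below matched lists, though not without genes that differ between tables (-0.20, percentile 3.86). Glutathione S-transferases (0.37, -0.41 rescaled, and -0.09), wax and lipid transfer genes (0.84 and 0.20, -0.30 rescaled at 96 h), jasmonate genes (0.59, -0.29 rescaled, and 0.59), sugar and starch genes (0.53, -0.11 rescaled, and 0.62) and autophagy genes (0.64 and 0.40, -0.03 rescaled at 96 h) did not stand apart. Within them the beta-amylase LOC_Os10g41550 went from 0.888 to 522 FPKM, the sucrose synthase LOC_Os03g22120 from 3.01 to 514 FPKM and LTPL102 (LOC_Os04g33920) from 0.418 to 726 FPKM at 96 h. Transposon-annotated genes had medians of 0.64 and 0.82, above matched lists at 96 h.

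Mahulata had 6035 genes at least 2-fold higher and 1901 at least 2-fold lower among 16911 genes at 48 h, and 6023 and 4069 among 17405 at 96 h. Rescaling gave 2572 higher and 3009 lower at 48 h and 3993 and 5220 at 96 h, and moved the share of higher genes from 76.0% to 46.1% and from 59.7% to 43.3%. The authors' deposited table lists 1866 genes up and 787 down at 48 h, and 2108 and 1973 at 96 h.

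Of the root markers with a value, LOC_Os02g51110, annotated as an aquaporin, reached at most 18.5 FPKM in the drought tables and LOC_Os02g40730, an ammonium transporter, 2.2 FPKM, and the rest of those with a value stayed under 1 FPKM. Shoot meristem and panicle markers with a value reached at most 0.317 FPKM. Of the scaling controls the actin gene LOC_Os03g50885 went from 67.5 to 82.9 FPKM in IR20 and from 61.8 to 148 FPKM in Mahulata at 96 h, and the ubiquitin-conjugating enzyme LOC_Os02g42314 from 43.1 to 48.1 and from 62.0 to 41.6 FPKM. The elongation factor Tu gene LOC_Os03g08010, another control, has no value in the IR20 drought tables and moved most at 48 h in Mahulata, from 97.9 to 560.2 FPKM, and went from 197 to 349 FPKM at 96 h, its 0 h value differing between the tables. The control list had medians of 0.31 and 0.22 in IR20 (-0.35 and -0.36 rescaled) and of 0.63 (-0.08 rescaled) and 0.83 in Mahulata, at 48 h and 96 h.

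**Figure D3:**
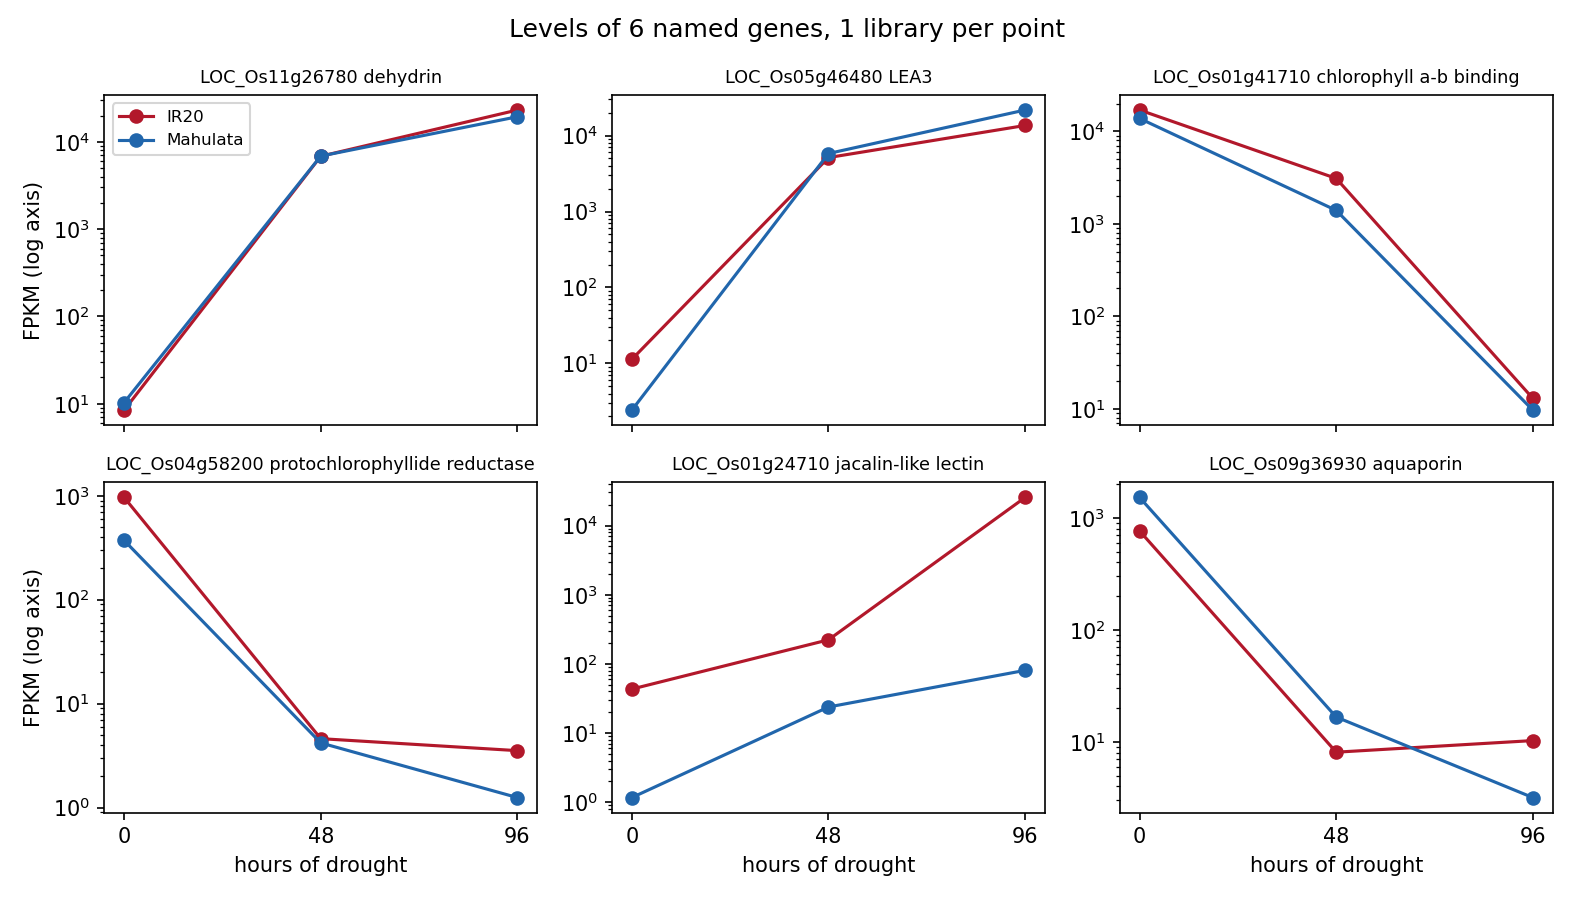
FPKM (y axis, log scale, each panel with its own range) of 6 genes at 0, 48 and 96 h of drought (x axis) in IR20 (red) and Mahulata (blue), 1 library per point, from the drought tables. The dehydrin LOC_Os11g26780 reached 23144 and 19377 FPKM at 96 h, while the chlorophyll a-b binding gene LOC_Os01g41710 was down to 12.9 and 9.66 FPKM.

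The 2 varieties shared most of the response. Across 15687 genes at 48 h the IR20 and Mahulata differences had r = 0.84 and rho = 0.78, and across 16200 genes at 96 h r = 0.90 and rho = 0.87; genes are not independent replicates. At 48 h 3777 genes were higher in both, of 5043 in IR20 and 5748 in Mahulata, against 1848 for independent lists, and 1389 were lower in both, against 265. At 96 h 4580 were higher in both (independent lists 2116) and 3221 lower in both (1007). These overlaps were not rescaled, and the median of all genes was above 0 in each variety. After rescaling, only 2608 genes in IR20 and 2572 in Mahulata were higher at 48 h, and 4715 and 3993 at 96 h. Part of the shared higher genes therefore rests on that common shift. Rescaled lower counts were larger, at 3833 and 3009 at 48 h and 5811 and 5220 at 96 h. The varieties share no library in these comparisons. Opposite changes were few, with 20 genes higher in IR20 and lower in Mahulata and 35 the reverse at 48 h, and 21 and 61 at 96 h.

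The third comparison set Mahulata against IR20 at each time. Before drought, at 0 h, clade A phosphatases 2C were higher in Mahulata in 5 of 8 cases (median 1.20, above all matched lists), with LOC_Os01g46760 at 1.25 FPKM in IR20 and 9.60 in Mahulata. Ribosomal protein genes leaned to IR20, with 49 of 333 lower in Mahulata (median -0.50), and so did chlorophyll synthesis genes (3 of 7 lower, median -0.98). Cell division and histone genes leaned to Mahulata (13 of 63 higher, median 0.33).

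The cytochrome P450 gene LOC_Os08g39640 was listed at 0 in IR20 and at 83.6 FPKM in Mahulata at 0 h. Its long locus (chromosome 8, 25007478 to 25134371) may hold other genes. The DnaJ gene LOC_Os08g35160 was at 0.0893 and 51.3 FPKM. The protein kinase gene LOC_Os11g35274 was at 196 FPKM in IR20 and 0.157 in Mahulata, the helix-loop-helix gene LOC_Os01g72370 at 97.4 and 0.628, and the metal transporter gene Nramp6 (LOC_Os07g15460) at 52.4 and 0.467 FPKM. The largest difference was that of the BURP domain gene LOC_Os05g12410, at 498 and 0.346 FPKM, whose value for a library differs over 1.5 times between tables. Protochlorophyllide reductase A (LOC_Os04g58200) was at 980.4 FPKM in IR20 and 359 in Mahulata, and the stay-green gene LOC_Os09g36200 at 4.82 and 18.0. Smaller shifts that stood apart from matched lists were those of cell wall expansion (-0.46), autophagy (0.45), the Calvin cycle (-0.29), wax and lipid transfer (-0.28), aquaporins (-0.27), auxin response (-0.26), photosystems (-0.24) and heat shock proteins (0.20). Of these, the heat shock call was lost with no floor (0.0655, percentile 83.9) and without genes that differ between tables (92.4), the autophagy call in the latter setting (97.3), and the aquaporin call with no floor (2.78), a floor of 5 FPKM (8.59) or a pseudocount of 0.1 FPKM (3.03). LEA and dehydrin genes did not stand apart (-0.20), though LOC_Os05g46480 was at 11.5 FPKM in IR20 and 2.33 in Mahulata.

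At 48 h the ribosomal protein genes leaned to Mahulata, with 58 of 291 higher (median 0.66, above all matched lists), and cell wall expansion genes did too (7 of 29 higher, median 0.73), though not with no floor (0.13, percentile 92.0), with a floor of 5 FPKM (0.75, percentile 90.6) or across tables (0.42, percentile 97.0). Stress transcription factors (-0.46), abscisic acid synthesis and breakdown (-0.38), autophagy (-0.37), photosystem (-0.33), LEA and dehydrin (-0.29), glutathione S-transferase (-0.22) and reactive oxygen (-0.12) lists leaned to IR20, few of their members by 2-fold. Sugar and starch genes also lay below matched lists, at 0.00 (-0.14 rescaled, percentile 2.68). Across tables the calls for LEA and dehydrin (6.08), abscisic acid (5.31), reactive oxygen (4.61), autophagy (3.21) and sugar genes (8.79) were lost, the percentile in brackets. So were those for glutathione S-transferases (-0.0275, percentile 7.59) and sugar genes (-0.0647, percentile 3.26) with a floor of 5 FPKM. Without genes that differ between tables, the calls for abscisic acid (6.0), reactive oxygen (8.70) and sugar genes (3.36) were lost. The abscisic stress-ripening gene LOC_Os04g34600 was at 41.0 FPKM in IR20 and 760.03 in Mahulata, and LOC_Os08g39640 again was listed at 0 in IR20 and at 52.7 FPKM in Mahulata. The glutathione S-transferase LOC_Os10g38630 and the thaumatin gene LOC_Os12g43490 were at 57.9 and 32.8 FPKM in IR20 and listed at 0 in Mahulata. The NAC gene LOC_Os03g60080 was at 521 and 253 FPKM, and the dioxygenase LOC_Os07g05940 at 102 and 42.0.

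At 96 h cell division and histone genes were higher in Mahulata in 19 of 46 cases (median 0.78), glutathione S-transferases in 14 of 32 (median 0.75) and senescence genes in 2 of 4 (median 1.30), and ethylene synthesis genes leaned the same way (0.68). With no floor the calls for glutathione S-transferases (0.10, percentile 91.5), senescence (0.44, percentile 92.8) and ethylene (0.33, percentile 95.6) were lost. Those for senescence (0.65, percentile 96.4), ethylene (0.42, percentile 97.4) and the Calvin cycle (-0.43, percentile 4.21) were lost across tables, and that for ethylene also with a floor of 5 FPKM (0.21, percentile 62.9) and without genes that differ between tables (0.66, percentile 97.1). Photosystem (-0.45) and Calvin cycle (-0.55) lists leaned to IR20; in the latter the lowest members, such as LOC_Os10g21268 (758 FPKM in IR20 and 113 in Mahulata), carry the annotation of the Rubisco large subunit, a plastid-genome gene. The jacalin-like lectin gene LOC_Os01g24710 (chromosome 1, 13903152 to 13904729) was at 27518 FPKM in IR20 and 84.5 in Mahulata, the largest difference among the genes that the 96 h variety table holds. The hevein gene HEV2 (LOC_Os04g41640) was at 635 and 3.05 FPKM, and the receptor-like kinase gene LOC_Os04g56430 at 1578 and 15.4. In the other direction the thaumatin gene LOC_Os12g43410, listed at 0 in IR20, was at 93.0 FPKM in Mahulata. The proteinase inhibitor II gene LOC_Os03g52370 was at 18.9 and 1086 FPKM, the glutathione S-transferase LOC_Os03g57200 at 12 and 185, and LOC_Os04g34600 at 3.26 and 189. The stay-green gene LOC_Os09g36200 was at 26.5 and 91.1 FPKM. LEA and dehydrin (0.03, -0.03 rescaled), clade A phosphatase (0.05, -0.02 rescaled) and ribosomal (0.02, -0.05 rescaled) lists did not stand apart.

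Some differences between the varieties were present at all 3 times. Of 6731 genes, 20 were at least 4-fold higher in Mahulata and 21 at least 4-fold higher in IR20 at each time. Some of these genes are listed at 0 in 1 variety at all 3 times, such as LOC_Os05g10414 in Mahulata and LOC_Os03g28250 in IR20. Whether such zeros reflect a lack of expression or reads that did not align was not tested. Between 0 h and 48 h, which share no library, 32 genes were 4-fold higher in Mahulata at both, against 1.13 for independent lists, and 45 in IR20, against 1.19. Chosen after its values were seen, the Bowman-Birk trypsin inhibitor BBTI4 (LOC_Os01g03340) was at 20.5, 206 and 239.8 FPKM in IR20 and listed at 0, then at 21.0 and 6.40 in Mahulata.

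In counts, Mahulata had 829 genes at least 2-fold higher and 1196 at least 2-fold lower than in IR20 at 0 h, 1314 and 569 at 48 h, and 1571 and 1096 at 96 h, of 16227, 12131 and 9839 genes. Rescaling gave 964 and 736 at 48 h, taking the share of higher genes from 69.8% to 56.7%. The authors' deposited table lists 479 genes up and 555 down in Mahulata at 0 h, 520 and 225 at 48 h, and 620 and 427 at 96 h. The variety tables hold only part of the genes: of those at 5 FPKM or more in both libraries in the drought tables, 2395 of 9469 are absent at 48 h and 3684 of 8701 at 96 h. Built across the drought tables instead, the split was 1362 higher and 1565 lower at 48 h and 2150 and 2663 at 96 h. Each library was first brought to the scale of the variety table by a constant factor. What changed was the gene set (16580 and 16356 genes) and the values of genes that differ between tables beyond that factor.

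The fourth comparison subtracted the IR20 response from the Mahulata response. At 48 h ribosomal protein genes responded higher in Mahulata in 205 of 343 cases (median 1.25, above all matched lists) and cell wall expansion genes in 22 of 45 (median 0.90). Clade A phosphatases 2C responded lower in Mahulata in 6 of 9 cases (median -1.26), starting from the higher 0 h level given above. Between varieties they were at a median of -0.08 at 48 h (7 measured, percentile 33.4), against 1.20 at 0 h. Their 48 h difference of responses may thus largely carry the 0 h gap. Of these phosphatases, LOC_Os01g46760 went from 1.23 to 17.7 FPKM in IR20 and from 6.57 to 12.3 in Mahulata, where the 0 h library is at 9.60 FPKM in the 0 h variety table. Autophagy (-0.77), stress transcription factor (-0.75), abscisic acid synthesis and breakdown (-0.70) and senescence (-0.62) lists were also below matched lists.

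Other lists apart at 48 h were chlorophyll synthesis (0.95), ethylene synthesis (0.55) and wax and lipid transfer (0.50) above, and glutathione S-transferases (-0.28) and photosystems (-0.17) below. Between varieties chlorophyll synthesis genes were at -0.98 at 0 h and -0.18 at 48 h (5 measured, not apart). Their difference of responses too may largely carry the 0 h gap. The photosystem call was lost without plastocyanin-like proteins and copies (-0.24, percentile 15.3), that for glutathione S-transferases with a floor of 5 FPKM (-0.0596, percentile 23.4), and those for senescence (3.21) and wax (96.8) without genes that differ between tables. The ethylene call was lost with no floor (percentile 93.6), a floor of 5 FPKM (88.3) and without genes that differ between tables (96.1). At 96 h ribosomal protein genes lay above (0.53, 110 of 352 higher and 52 lower). So did aquaporins (0.81), ethylene synthesis (0.67), pathogenesis-related (0.58) and wax and lipid transfer genes (0.47). Clade A phosphatases (-0.73) and photosystems (-0.21) lay below. The 48 h and 96 h differences subtract the same 0 h libraries, so they are not independent. Between varieties the ribosomal and phosphatase lists were at 0.02 and 0.05 at 96 h, against -0.50 and 1.20 at 0 h. Their 96 h differences of responses may thus largely carry the 0 h gap. Of the marker lists, cytosolic ribosomal genes had a median of 0.91 and ribosomal copies of plastid-genome genes of -1.47. LEA and dehydrin genes did not stand apart at 48 h (0.23) or 96 h (0.33). The 96 h calls for ethylene synthesis (-0.0294, percentile 50.5) and pathogenesis-related genes (0.0433, percentile 82.1) were lost with no floor. That for photosystems was lost with a floor of 5 FPKM (percentile 2.64), without plastocyanin-like proteins (2.98), and without these and plastid-genome copies (0.10, percentile 53.2).

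The protein kinase gene LOC_Os11g35274 went from 193 to 0.773 FPKM in IR20 and from 0.163 to 0.411 in Mahulata at 48 h, near its floor in Mahulata throughout. The cytochrome P450 gene LOC_Os08g39730 went from 1.25 to 45 FPKM in IR20 and from 0.052 to 0.464 in Mahulata. At 96 h LTPL63 (LOC_Os07g29230) had the largest difference of responses among annotated genes (-12.64): it was listed at 0 at 0 h in both varieties and reached 11099.5 FPKM in IR20 and 0.736 in Mahulata. The hevein gene LOC_Os04g41640 went from 0.454 to 587 FPKM in IR20 and from 0.46 to 2.91 in Mahulata, the endo-beta-mannanase gene OsMan05 (LOC_Os03g61280) from 3.80 to 411 FPKM in IR20 and from 1.39 to 0.27 in Mahulata, and the O-methyltransferase gene LOC_Os11g19840 from 0.222 to 0.419 FPKM in IR20 and from 0.936 to 159 in Mahulata. The lectin gene LOC_Os01g24710 went from 43.2 to 25448 FPKM in IR20 and from 1.10 to 80.6 in Mahulata, and the thaumatin-like gene LOC_Os03g14050 from 1.54 to 710.4 and from 1.53 to 144. The glycine-rich protein gene LOC_Os06g21230 went from 245 to 279.8 FPKM in IR20 and from 1.69 to 267 in Mahulata, but its value for a library differs over 1.5 times between tables, and so do those of the glutamine synthetase LOC_Os03g50490 (6.19) and of LOC_Os06g08560, annotated multidrug resistance-associated protein 11 (-7.77). In all 2530 genes responded at least 2-fold higher in Mahulata and 1296 lower among 17875 at 48 h, and 2704 and 2372 among 18575 at 96 h. The 48 h value holds the all-gene median of 0.15, and each response comes from its own table, which the authors scaled separately.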

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

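The following genes moved in opposite directions in the 2 varieties. The difference was not tested, since each group has 1 library, and the genes were picked for the size of their difference. At 48 h 4 genes were higher in IR20 and lower in Mahulata. LOC_Os01g45110, an anthocyanin glucosyltransferase, went from 1.21 to 4.45 FPKM in IR20 and 6.27 to 0.161 in Mahulata (difference -3.95). LOC_Os01g61070, a heavy metal-associated domain gene, went from 13.6 to 66.6 FPKM in IR20 and 98.6 to 12.4 in Mahulata (difference -5.10). LOC_Os03g52910, a UPF0114 domain gene, went from 2.94 to 29.4 FPKM in IR20 and 20.2 to 3.90 in Mahulata (difference -5.06). LOC_Os07g37400, the F-box gene OsFBX257, went from 0.0433 to 3.98 FPKM in IR20 and 13.3 to 1.09 in Mahulata (difference -5.03). Moving the other way at 48 h were 3 genes whose value for a library differs over 1.5 times between tables. LOC_Os02g05470, a CCT motif gene, went from 161 to 16.6 FPKM in IR20 and 13.9 to 37.6 in Mahulata (difference 4.57). LOC_Os05g12400, a BURP domain gene, went from 624 to 85.7 FPKM in IR20 and 49.5 to 222 in Mahulata (difference 4.99). LOC_Os05g12640, another BURP domain gene, went from 80.0 to 2.15 FPKM in IR20 and 57.0 to 319 in Mahulata (difference 7.15). At 96 h 2 such genes, also differing between tables, moved the same way. LOC_Os05g49900, a 3-ketoacyl-CoA synthase, went from 19.3 to 3.06 FPKM in IR20 and 0.17 to 15.9 in Mahulata (difference 6.18). LOC_Os06g14400, an aminocyclopropane carboxylate oxidase homolog, went from 82.0 to 3.44 FPKM in IR20 and 9.79 to 27.6 in Mahulata (difference 5.63).

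The lists of genes not expressed in the IR20 tables, all at 0, hold 1 gene at 48 h and 8 genes at 96 h that another table puts at 1 FPKM or more for the same library. The highest is the F-box gene OsFBX66 (LOC_Os02g56760), at 327 FPKM for IR20 at 96 h in the variety table.

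Of the patterns weighed, the tests on library scaling, on nuclear-encoded plastid ribosomes and on genes left out were chosen after the result was seen. LEA and other seed-type maturation genes were abundant in leaf at 96 h, with LOC_Os11g26780 at 23144 and 19377 FPKM. Grain tissue in the leaf samples would bring abundant storage transcripts, which is argued against, since the median of all listed storage genes was 0.826% of that of the maturation genes in IR20 and 0% in Mahulata, and their sums were 37.4 and 31.1 FPKM against 105787 and 85028 FPKM. The 3 storage genes above the floor did go up with the maturation genes (medians 3.41 and 2.91), to median levels of 11.8 and 10.03 FPKM against 145 and 172 FPKM for maturation genes above it. Their median level equalled their highest in each variety, so these genes share a value. They may be 1 measured locus entered more than once, in the sums too. Rescaling left LEA medians of 6.03 in Mahulata and 6.29 in IR20. It shifts a pair by 1 factor, 0.60 on the log2 scale in each variety at 96 h, so this outcome was near certain beforehand. The values show only that 1 factor of that size is too small to give these medians. Drought itself, the factor of the design, stays open as untested, with 1 library per group.

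Ribosomal protein genes responded higher in Mahulata than in IR20 at 48 h, by a median of 1.25. The list lay at percentile 100 among lists matched on expression and genomic span, which argues against a bias by span. Span is the length of the locus, not of the transcript, so a bias by transcript length stays undecided. The rescaled median was still 1.05 above that of all genes. A constant factor moves the list and all genes nearly alike, so it could not set the list apart. Rescaling could hardly change that gap and is no separate test of library scaling. Cytosolic members exceeded the plastid list by 1.28, a gap that decides nothing because that list was mostly nuclear copies of plastid-genome genes. Against the 22 members taken as nuclear-encoded plastid by name the gap was -0.10. In the difference of responses their quartiles were 0.68 and 1.84, against 1.05 and 1.57 for cytosolic members. This argues against a variety difference in cytosolic ribosomes alone. Within each variety the medians of the kinds lay apart (2.04 against -0.17 in Mahulata and 0.68 against -0.51 in IR20), with the plastid members split. Sampling, library preparation and variety stay open and untested, with Mahulata below IR20 at 0 h (-0.50) and above it at 48 h (0.66), and so does time of day, for clock genes had 0 of 7 members 2-fold apart in the difference of responses at 48 h (quartiles -0.36 and 0.12), yet LOC_Os02g40510 was at 6.25 FPKM in IR20 and 16.7 in Mahulata at 0 h.

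The variety split in the deposited tables leaned to Mahulata at 48 h and 96 h. Genes left out of those tables leaned the other way: the genes kept had a median above theirs by 0.30 at 48 h and 0.23 at 96 h. The absence of these genes is a candidate cause of the lean, and why they are absent was not tested. No biological explanation was tested for this pattern.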

How the results depend on the processing

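Of 1651 list medians recomputed under an alternative, 1532 kept their side of the limits with no called median changing sign, 54 lost the call with the sign kept and 52 gained one. In the other 13 a called median changed sign, and 7 of these lost the call too. Of 105 called medians, 37 lost the call or changed sign somewhere. Medians that were not called are not among the sign changes counted, and many of them turned negative on rescaling. Leaving out replicates was not possible, because each group has 1 library. No paired analysis was possible because no result comes from a test and the groups have no second replicate. Where no cause is given, the cause was not tested. Depth limits low genes most, and the Mahulata 0 h and 48 h libraries had the lowest relative depth.

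Stricter thresholds gave fewer genes by construction. At 4-fold the higher and lower counts were 1661 and 1054 for IR20 48 h, 3145 and 2448 for IR20 96 h, 1631 and 628 for Mahulata 48 h, 2659 and 1950 for Mahulata 96 h, 128 and 260 for 0 h between varieties, 152 and 114 for 48 h, 306 and 245 for 96 h. The authors' deposited table lists 2050 and 1332 for IR20 48 h, 2504 and 2040 for IR20 96 h, 1866 and 787 for Mahulata 48 h, 2108 and 1973 for Mahulata 96 h, 479 and 555 for 0 h between varieties, 520 and 225 for 48 h, 620 and 427 for 96 h. Rescaling gave 2608 higher genes for IR20 48 h, 2572 higher and 3009 lower for Mahulata 48 h, and 3993 higher for Mahulata 96 h. With a pseudocount of 0.1 FPKM, genes at least 2-fold higher, Mahulata minus IR20 at 0 h, numbered 1336. For genes at least 2-fold higher, Mahulata minus IR20 at 48 h, it gave 2122, and a floor of 5 FPKM gave 849. For genes at least 2-fold lower, Mahulata minus IR20 at 48 h, the pseudocount gave 854. It also gave 3881 for genes at least 2-fold higher, difference of responses at 48 h, and 3567 for genes at least 2-fold lower, difference of responses at 96 h. The floor of 5 FPKM left 785 genes at least 2-fold lower, Mahulata minus IR20 at 0 h, and 716 genes at least 2-fold lower, Mahulata minus IR20 at 96 h. Of the alternatives chosen after seeing the data, counting transcripts gave 8259 for genes at least 2-fold higher, IR20 48 h minus 0 h, and 9121 for genes at least 2-fold higher, Mahulata 48 h minus 0 h. Building the variety difference across tables gave 1565 lower at 48 h and 2663 at 96 h.

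Numbers of lists above matched lists between varieties went from 2 to 1 at 48 h and from 4 to 1 at 96 h with no floor. Without genes that differ between tables, a setting chosen after seeing the data, those above went from 4 to 2 at 0 h, those below from 8 to 5 at 48 h, and those above in the difference of responses at 48 h from 5 to 3. Built across tables, 1 list lay above and 5 below at 48 h. A floor of 5 FPKM left 1 of 2 below in the difference of responses at 96 h.

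Of the called medians that changed sign, cell division in IR20 at 48 h went from 0.04 to -0.0468 with no floor, -0.55 rescaled and -0.11 without genes that differ between tables, and in Mahulata at 48 h from -0.05 to 0.0171 with no floor. With a floor of 5 FPKM, ethylene synthesis in IR20 at 48 h went to 0.15 and auxin response in Mahulata at 48 h to 0.21. Ribosomal protein genes in Mahulata at 96 h went to -0.36 rescaled. Sugar and starch genes between varieties at 48 h went to -0.0647 with a floor of 5 FPKM, -0.14 rescaled, -0.0027 without genes that differ between tables and -0.078 across tables. In the difference of responses at 96 h, ethylene synthesis went to -0.0294 with no floor and the photosystem list to 0.10 without plastocyanin-like proteins and plastid-genome copies, a split chosen after seeing the data.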

Other observations

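Genes on the nuclear chromosomes that are annotated as copies of plastid-genome genes moved apart from the nuclear photosynthesis genes, as seen in lists written after the data were seen. At 96 h ribosomal copies were higher in 53 of 60 cases in IR20 (median 1.75) and in 9 of 51 in Mahulata (median 0.18, -0.28 rescaled). Their response was lower in Mahulata in 43 of 60 cases (median -1.47). Photosystem copies had medians of 0.66 in IR20 and 0.23 in Mahulata (-0.23 rescaled) at 96 h. The whole plastid ribosomal list, copies included, had medians of 1.47 and 0.05 (-0.35 rescaled). Reads of the plastid genome and of such copies are nearly alike, and which of them were counted was not tested.

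At 96 h the pathogenesis-related list did not stand apart between the varieties (0.40, percentile 96.9, 16 higher and 9 lower of 38), and single members went both ways. The chitinase CHIT3 (LOC_Os04g41680) was at 71.7 FPKM in IR20 and 0.663 in Mahulata at 96 h, and the chitinase CHIT16 (LOC_Os03g04060) at 0.818 and 24.5. The cupin gene LOC_Os08g08970 was at 245 FPKM in IR20 and 2.44 in Mahulata. The heat shock list did not stand apart either (-0.06, percentile 12.3, 10 higher and 16 lower of 63), with LOC_Os01g04370 at 132 and 5.35 FPKM and LOC_Os03g06170 at 20.7 and 2.24. The aquaporin LOC_Os10g35050, higher in both varieties under drought, was at 309 FPKM in IR20 and 43.6 in Mahulata at 96 h.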
